A study of Rattus norvegicus with 2 samples.

How the data were processed

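RNA of the hypothalamus of male and female SHR was measured, as 1 pool of 5 rats per sex on 1 single-colour (Cy3) Agilent array each; the labels describe killing under ether followed by decapitation, and dissection of the hypothalamic block under a microscope by a single operator. Per the file headers, each array file holds the scanner software's processed spot signal, an intensity with the background subtracted and no scaling between arrays, together with spot and local background medians and flags. The headers name Feature Extraction 11.5.1.1 with protocol GE1_1105_Oct12 and design build rn4, whereas the submitters' processing notes name Feature Extraction 9.1. The deposited series matrix holds intensity values; its scaling is not given in the sources used here, and it was checked against the array files. Its 42947 values per array equalled the processed signal divided by the array's 75th percentile and multiplied by 100, on a linear scale. They were those of spots well above background on at least 1 array with no outlier flag on either. Both arrays were on 1 slide, at positions 1 and 2, and were scanned together, so slide and scan did not differ between the sexes.

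Each array had 62976 spots, of which 58717 were for rat transcripts (45598 probes; 43279 on 1 spot, 969 on 2 and 1350 on 10). Spots with an outlier flag on either array (664) were left out, and no spot was saturated. The software's flags called 500 outlier spots on the male array and 425 on the female array. Spike-in RNAs gave a log signal to log amount slope of 0.98 on both arrays (R2 0.989 and 0.990), and repeat spots had a median coefficient of variation of 3.59% and 3.53%. A probe with repeat spots counted as well above background when more than 50% of its spots did; the lowest signal of such a probe was 15.1 units on the male array and 12.9 units on the female array. Log2 signals were centred on each array's 75th percentile over rat transcript spots and averaged over a probe's spots. Probes were given gene symbols by matching their RefSeq accessions to a gene table of assembly GRCr8, used for names and chromosomes only, because the array design names another build. Symbols matched 21109 of 45598 probes (46.3%), and unmatched probes kept their accession as an unnamed transcript. Where a gene had several probes, the one with the highest mean signal was used, which gave 39500 genes and transcripts, 16096 of them named. A probe was measured when well above background on at least 1 array (26109, of which 12614 named), and on both for medians (24140, of which 12054 named). Where 1 side was dim, it was raised to that array's lowest probe signal, and the difference became a bound.

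The comparison was male minus female, with a size threshold of 2-fold and no test. Technical noise was estimated from repeat spots of a probe within an array. The SD of a difference on 1 spot was 0.071 above the 75th percentile and 0.085 at log2 signals of -2 to 0. It was 0.12 at -4 to -2 and 0.20 at -6 to -4. Below -6 it was 0.46, from 6 probes only. It covers spot printing and scanning only, not animals or arrays. The threshold, scaling, gene lists and the rule for named genes were set before the data were examined. The rule took the 12 named genes per direction with the largest difference on both arrays and well-measured probes of 1 sign, and the 4 per sex with the largest bounds. From every list it took the members at least 2-fold apart, or otherwise the 2 with the largest difference, and it added a set of neuropeptide, steroid receptor and blood pressure genes whatever their values; not every gene it took is printed. The same rule was then applied without spots in patches, a choice made after the data were seen. The 24 lists covered Y-linked genes, X genes that escape inactivation, neuropeptide and hormone precursors, their receptors, steroid receptors and enzymes, the renin-angiotensin system, nitric oxide and cGMP, catecholamine and serotonin, amino acid transmitters, oxidative stress, microglia and inflammation, immediate early genes, hypothalamic transcription factors, pituitary, thalamus, cortex and hippocampus, striatum and amygdala, choroid plexus and ependyma, oligodendrocytes, astrocytes and tanycytes, neurons, endothelium with mural cells and meninges, red blood cells, and common reference genes. Matches ranged from 4 of 10 Y-linked genes to all 53 amino acid transmitter genes. A list with at least 5 members well above background on both arrays got a median and a percentile among 10000 random lists of the same size, drawn within 20 signal bins. A second list of 34 meningeal genes, of which 23 were well above background on both arrays, was written after the first results and before its own values were seen. To test for signal added in patches, repeat spots of probes with at least 8 spots and a signal under the 75th percentile were compared with the same probe's median outside patches on each array.

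Patches were defined from spot positions, with the 18 nearest measured spots of other probes and a minimum of 2, or 3 as an alternative. Other alternatives were normexp background correction (limma 3.58.1, R 4.3.3, offset 50), quantile normalization, median centring, loess centring on mean signal, the deposited matrix values, thresholds of 1.5-fold and 3-fold, filters on dim probes, outlier spots kept, the mean over probes, probes in place of genes, and random lists without matching. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. The steps were tested on simulated data for the male against female comparison over 25481 genes. They called 97 of 100 genes made 2.5-fold different and 100 of 100 made 4-fold different. They also called 15 of 25281 unchanged genes, and returned 0.30 for a list shifted by 0.3. The simulated male array took its background flags from the female array, so the simulation did not cover bounds. In the data, 278 genes called in the male direction and 148 in the female direction were above background on both arrays. Of 200 unchanged lists 6 fell outside the middle 95% of random lists. With added local signal of 150 units on 40 discs, over 25473 genes, 270 unchanged genes were called, and over 24667 genes without spots in patches 61 were called; 263 of 317 spots (83.0%) driven past 2-fold by the added signal were found in patches.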

Results

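Gene expression was measured in the hypothalamus of male and female spontaneously hypertensive rats (SHR), an inbred strain that develops high blood pressure with age. Each sex was represented by 1 RNA pool, made from 100 ng of RNA from each of 5 rats aged 9 weeks, and each pool was measured on 1 single-colour microarray. There were no replicates, so no test was run and every difference describes these 2 pools only. Of 58717 spots for rat transcripts on each array, 42034 (71.6%) were well above background on the male array and 42874 (73.0%) on the female array. The 75th percentile of spot signal was 2203 units on the male array and 2254 units on the female array, over a median local background of 33 units on both. The number of arrays limits the precision of every value. Differences are male minus female log2 signal after each array was scaled to its 75th percentile, so that positive values are higher in the male pool. Where a gene was well above background in 1 pool only, the other pool was raised to the lowest probe signal that counted as well above background on its array, and the fold is written as "at least".

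The comparison of the pools addresses the series' question of how expression in a brain region that controls the circulation differs between the sexes of this strain. Genes of meningeal fibroblasts and red blood cells were higher in the male pool. Those of the choroid plexus and ependyma were higher by less, with a list median of 0.24, and of 0.13 with normexp. Among these genes were the collagen genes Col1a1 (2.30-fold) and Col1a2 (2.44-fold), the growth factor gene Igf2 (2.65-fold) and the haemoglobin gene Hbb (1.83-fold). Most genes for neuropeptides and their receptors were slightly lower in the male pool, with a median log2 difference of -0.11 over 47 precursors. Kiss1, which encodes the kisspeptin that drives gonadotropin release, was lower by a log2 difference of -1.22, and of -0.40 with normexp background correction. Tshb and Cga, which encode the subunits of thyrotropin, were 12.4-fold and 4.08-fold higher in the male pool, and 3.49-fold and 3.60-fold with normexp. Y-linked Eif2s3y, which encodes a translation initiation subunit, was at least 29.9-fold higher in the male pool, and 6.65-fold with normexp.

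The bulk of the transcriptome was close between the pools. Over 24140 genes and unnamed transcripts well above background on both arrays, the median log2 difference was -0.016, 5% lay below -0.28, 5% above 0.34, and 96.6% were within 1.5-fold. Across these genes, which are not independent replicates, Pearson's r of log2 signal between the arrays was 0.993. Of 26109 genes and unnamed transcripts measured on at least 1 array, 662 were at least 2-fold higher in the male pool and 428 in the female pool. Named genes made up 238 and 126 of these. Of the 1090 in total, 972 had a mean log2 signal over both arrays of -4 or lower relative to the 75th percentile. A low signal on 1 array lowers this mean, so a large difference raises the count by construction. Spots at least 2-fold apart lay together on the slide: 1183 of 1602 such spots (73.8%) were in patches, against 10.5% of measured spots under 2-fold. A spot counts as in a patch when at least 2 of the 18 nearest measured spots of other probes also differed at least 2-fold in 1 direction. Without spots in patches, an alternative chosen after the positions were seen, 108 genes and transcripts were at least 2-fold higher in the male pool and 31 in the female pool, of which 107 and 31 were among the 662 and 428. With normexp, the difference of 89 of 96 genes followed singly at a mean log2 signal of -4 or lower shrank over 1.5 times, against 8 of 78 brighter genes. The offset of 50 units that normexp adds shrinks log differences of dim genes by construction.

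**Figure D1:**
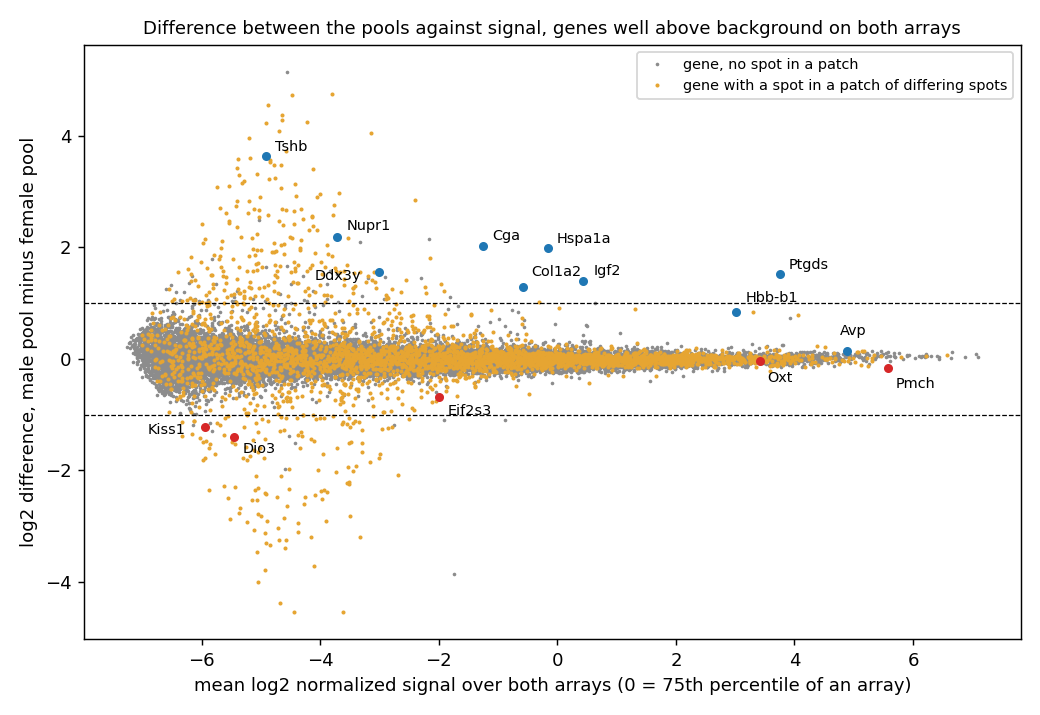
Log2 difference of each gene or unnamed transcript well above background on both arrays (y axis, male minus female) against its mean log2 signal relative to the 75th percentile (x axis), 1 point per gene. The median is -0.016, and of the 1090 genes and transcripts at least 2-fold apart (dim-side bounds included), 972 lie below a mean log2 signal of -4.

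**Figure D2:**
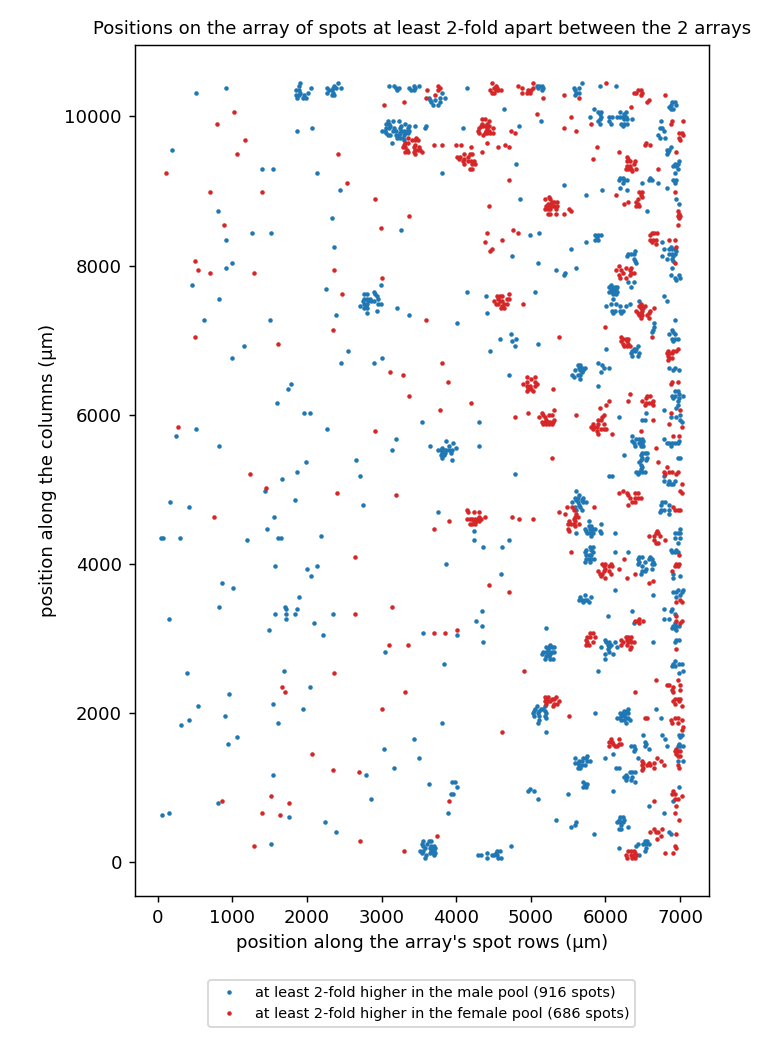
Positions on the array, in micrometres, of spots at least 2-fold higher in the male pool (916 spots, blue) or in the female pool (686 spots, red), 1 point per spot. The points form compact patches of a single direction, and 7.41% of measured spots in spot rows 257 to 384 (x axis, right) were at least 2-fold apart against 1.79% in rows 1 to 256.

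Some genes of the Y chromosome differed widely between the pools. Besides Eif2s3y, the RNA helicase gene Ddx3y was 2.93-fold higher in the male pool on its brightest probe and at least 12.9-fold higher on its second probe. Ube1y1, which encodes a ubiquitin-activating enzyme, was well above background in the male pool only, at a bound of 0.45 that was within its technical SD of 0.46. Tspy1, a testis-specific gene, was at 0.16 on a dim probe, and Uty was not well above background on either array. Among unnamed transcripts outside patches, LOC103694537 on the Y chromosome was at least 38.9-fold higher in the male pool, and XM_008773698 was 35.6-fold higher. The noncoding transcript model XR_147198 was at least 333-fold higher in the female pool and XR_597648 was 14.5-fold higher there. The first is a locus identifier without a gene name and the other 3 matched no symbol; all were chosen after their values were seen. Of the X-linked genes that can escape X inactivation, all 4 that were well above background on both arrays were lower in the male pool. These were Eif2s3 at -0.68, with -0.52 on its second probe, Zfx at -0.20, Usp9x at -0.12 and Uba1 at -0.03. The last 2 encode a deubiquitinase and a ubiquitin-activating enzyme. Uba1 was within its technical SD of 0.071, Usp9x was at 1.67 technical SD, and Zfx was about at its technical SD of 0.20. With normexp Zfx was at -0.015. Jpx, a noncoding activator of Xist, was well above background in the female pool only, with a bound of -0.21, and its spot was in a patch. Of all 381 X-linked genes well above background on both arrays, 148 were higher and 233 lower in the male pool. Their median log2 difference was -0.039, lower than all but 0.06% of random lists. This median was -0.016 with normexp and -0.070 with median centring.

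Gene lists were compared with 10000 random lists of the same size and similar signal, and the percentile of a list's median among theirs describes these 2 arrays, not the sexes. The list of endothelium, mural cells and meninges had 32 genes higher and 5 lower in the male pool, with a median of 0.26 (percentile 100). The list was divided by cell type after the first results were seen. Its 13 fibroblast genes were all higher in the male pool, from 0.50 to 1.82 with a median of 0.94. Its 15 endothelial genes had a median of 0.13 and its 8 mural genes 0.10. Col1a1, Col1a2 and Col3a1, which encode fibrillar collagens, were at 1.20, 1.29 and 1.21. The second Col1a1 probe was at 1.39, and Col3a1 was measured on 9 spots. Slc22a6, which encodes an organic anion transporter, was at 1.48. Igf2, which is also in the choroid plexus and ependyma list, was at 1.41. Ogn, which encodes the proteoglycan osteoglycin, was at 1.82 on a spot in a patch and at 1.60 on a probe outside patches. Slc6a13, which encodes a GABA transporter of the meninges, was at 1.62 on a spot in a patch. In the choroid plexus and ependyma list, 14 genes were higher and 4 lower in the male pool, with a median of 0.24 (percentile 100; 0.13 with normexp). Igfbp2, which encodes an insulin-like growth factor binding protein, was at 1.02, with 1.06 on its spot outside patches. The potassium channel gene Kcnj13 was at least 3.82-fold higher, near the background. Ttr, the abundant transthyretin transcript of the choroid plexus, differed by 0.23. Of the red blood cell genes 5 were higher and 2 lower, with a median of 0.84 (percentile 100), and of 0.45 with normexp. Among them the haemoglobin genes Hba-a2 and Hbb were at 0.84 and 0.87, and at 0.81 and 0.85 with normexp. The dimmer haemoglobin chaperone gene Ahsp was at 0.88, and at 0.45 with normexp.

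Glial and immune genes were also higher in the male pool, by less. In the oligodendrocyte list 26 genes were higher and 2 lower, with a median of 0.14 (percentile 100). The myelin gene Mog was at 0.18. Enpp6, a phosphodiesterase gene of newly formed oligodendrocytes, was at 0.52 on a spot in a patch, the gap junction gene Gjb1 was at 0.37 and the myelin protein gene Pllp at 0.33. The astrocyte and tanycyte list had 18 genes higher and 5 lower, with a median of 0.069 (percentile 100.0; 0.039 with median centring). Vim, which encodes the intermediate filament vimentin, was at 0.46 over 10 spots, and Gfap was at 0.34. Gpr50, an orphan receptor gene of tanycytes, had a bound of -0.61. In the microglia and inflammation list 28 genes were higher and 8 lower, with a median of 0.13 (percentile 100). Among genes for antigen presentation on MHC class II, Cd74, the invariant chain, was 2.98-fold higher over 8 spots outside patches. RT1-Da was at least 3.63-fold higher, and RT1-Bb was at a log2 difference of 0.92. Tnf, which encodes tumour necrosis factor, was at -2.81 on a single spot in a patch. Immediate early genes, which are induced within minutes of cell stimulation, had 24 members higher and 7 lower, with a median of 0.14 (percentile 100). Atf3 was at 0.87 over 2 spots, Fos at 0.57 and Nr4a1 at 0.57. Fosl1 at 2.59 (0.63 with normexp) and Fosl2 at 1.37 were on spots in patches, and the other Fosl2 probes lay between 0.17 and 0.26.

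Neuronal genes were slightly lower in the male pool. In the neuron list 2 genes were higher and 23 lower, with a median of -0.060 (percentile 1.19, and 6.75 without matching on signal; -0.091 with median centring). The synaptic vesicle release gene Snap25 was at -0.15, and the neurofilament gene Nefh was at 0.18. Of the 47 neuropeptide and hormone precursors 13 were higher and 34 lower, and their median of -0.11 was at percentile 0 (-0.067 with normexp). Crh, which starts the stress hormone axis, was at -0.40 on a spot in a patch and at -0.54 on its second probe. Hcrt, the orexin gene, was at -0.32, Gnrh1 at -0.32 and Pmch, the melanin-concentrating hormone gene, at -0.17. Npvf, which encodes gonadotropin-inhibitory peptides, was at -0.63, and Tac3, the neurokinin B gene, at -0.43. Ghrh, the growth hormone releasing hormone gene, was the precursor with the largest difference towards the male pool among the 47, at 0.60, with its other probes at 0.70 and 0.67. The blood pressure hormone gene Avp was at 0.14, Pomc at 0.24, Sst at 0.20 and Agrp at 0.17 on a spot in a patch, while Oxt at -0.03, Trh at -0.02 and Npy at -0.08 were close to 0. Kiss1 was dim, at 1.07% and 2.49% of the 75th percentile in the male and female pools.

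Neuropeptide and hormone receptors had 14 members higher and 31 lower, with a median of -0.11 (percentile 0.010; -0.065 with normexp). The vasopressin receptor gene Avpr1a was at -0.44, the opioid receptor gene Oprk1 at -0.57 and the somatostatin receptor gene Sstr2 at -0.99, the last on a spot in a patch; with normexp they were at -0.21, -0.15 and -0.45. Crhr2, a receptor gene of the stress axis, had a bound of 0.96 near the background, and 0.23 with normexp. Transcription factors that pattern the hypothalamus had 10 members higher and 24 lower, with a median of -0.11 (percentile 0.20), of -0.15 without spots in patches and of -0.058 with normexp. Lhx8 was at -0.58, and Barhl1 was at -0.70 with a technical SD of 0.46, but at -0.17 with normexp. The eye and pituitary regulator Six6 was at least 20.4-fold lower in the male pool on a spot in a patch.

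Lists tied to blood pressure control had medians close to 0. In the renin-angiotensin list 6 genes were higher and 9 lower, with a median of -0.014 (percentile 51.1). Agt, the angiotensin precursor, and Ace, the converting enzyme, were both at -0.01 and changed sign between scalings. The angiotensin receptor gene Agtr1a was at -0.44, and the dim peptidase genes Enpep and Prcp were at 0.75 and 0.48; with normexp they were at -0.16, 0.23 and 0.18, and the technical SD of both peptidase genes was 0.46. Nitric oxide and cGMP genes had a median of -0.029 (percentile 32.1; 8 higher, 11 lower), with Nos1, the neuronal nitric oxide synthase, at 0.36 and Gucy2c, a guanylate cyclase gene, at least 3.92-fold higher in the male pool near the background. Catecholamine and serotonin genes had a median of -0.020 (percentile 44.2; 14 higher, 16 lower), and -0.089 (percentile 0.89) without spots in patches. Th, the rate-limiting enzyme of catecholamine synthesis, was at -0.09, the beta-adrenergic receptor gene Adrb1 at -0.35, the dopamine receptor gene Drd4 at a bound of 0.84 and the serotonin receptor gene Htr4 at 0.78 on a spot in a patch; with normexp the last 3 were at -0.15, 0.19 and 0.26. Steroid receptors and enzymes had a median of -0.010 (percentile 63.0; 11 higher, 13 lower), which changed sign with normexp background correction. The progesterone receptor gene Pgr was at 0.00 with a sign that changed between scalings, while Esr1, Esr2 and Oxtr were not well above background on either array. Hsd3b1, a steroid dehydrogenase gene, was at least 4.33-fold lower in the male pool on a spot in a patch, and 1.55-fold with normexp. Oxidative stress and antioxidant genes had a median of 0.032 (percentile 99.5; 24 higher, 17 lower; 0.0016 with median centring), and Gclm, which encodes a subunit of the glutathione-making ligase, was at least 3.28-fold higher near the background. Amino acid transmitter genes had a median of -0.040 (percentile 9.66; 18 higher, 32 lower; -0.020 with normexp and -0.071 with median centring), with the GABA synthesis genes Gad1 and Gad2 at -0.16 and -0.27 and the GABA receptor gene Gabre at least 4.01-fold higher on a spot in a patch (1.55-fold with normexp).

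Markers of neighbouring brain regions went both ways. The striatum and amygdala list had 5 genes higher and 13 lower, with a median of -0.086 (percentile 0.70, and 2.71 with normexp). It included the retinoid receptor gene Rxrg at -0.27. Cortex and hippocampus genes had 3 higher and 15 lower, with a median of -0.086 (percentile 3.84), and of -0.038 with normexp. The percentile was 1.68 with normexp, 2.47 with quantile normalization and 2.25 without matching on signal. Cux2, a cortical transcription factor gene, was at 2.96 on a spot in a patch. Thalamus genes had 7 higher and 3 lower, with a median of 0.023 (percentile 89.7) that changed sign with median centring and with the mean over probes; Gbx2 was at 0.15, with -0.22 on its second probe, and Tnnt1 at -0.11. Common reference genes had a median of 0.018 (percentile 79.0; 12 higher, 7 lower), which changed sign with median centring, with Rplp0 at 0.13 on a spot in a patch. The pituitary list had 4 genes higher and 2 lower, with a median of 0.22 (percentile 99.7), of 0.095 (percentile 92.8) with dim members at their bound and of 0.95 with the mean over probes. Besides Tshb at 3.64 and Cga at 2.03, Lhb, which encodes the luteinising hormone subunit, was at 0.35 and Pou1f1, a regulator of pituitary hormone genes, was at -0.32. Cga and Pou1f1 were on spots in patches, and the Tshb spot was not. Prl, the prolactin gene, was well above background in the female pool only, at least 7.91-fold higher there, on a single spot in a patch.

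**Figure D3:**
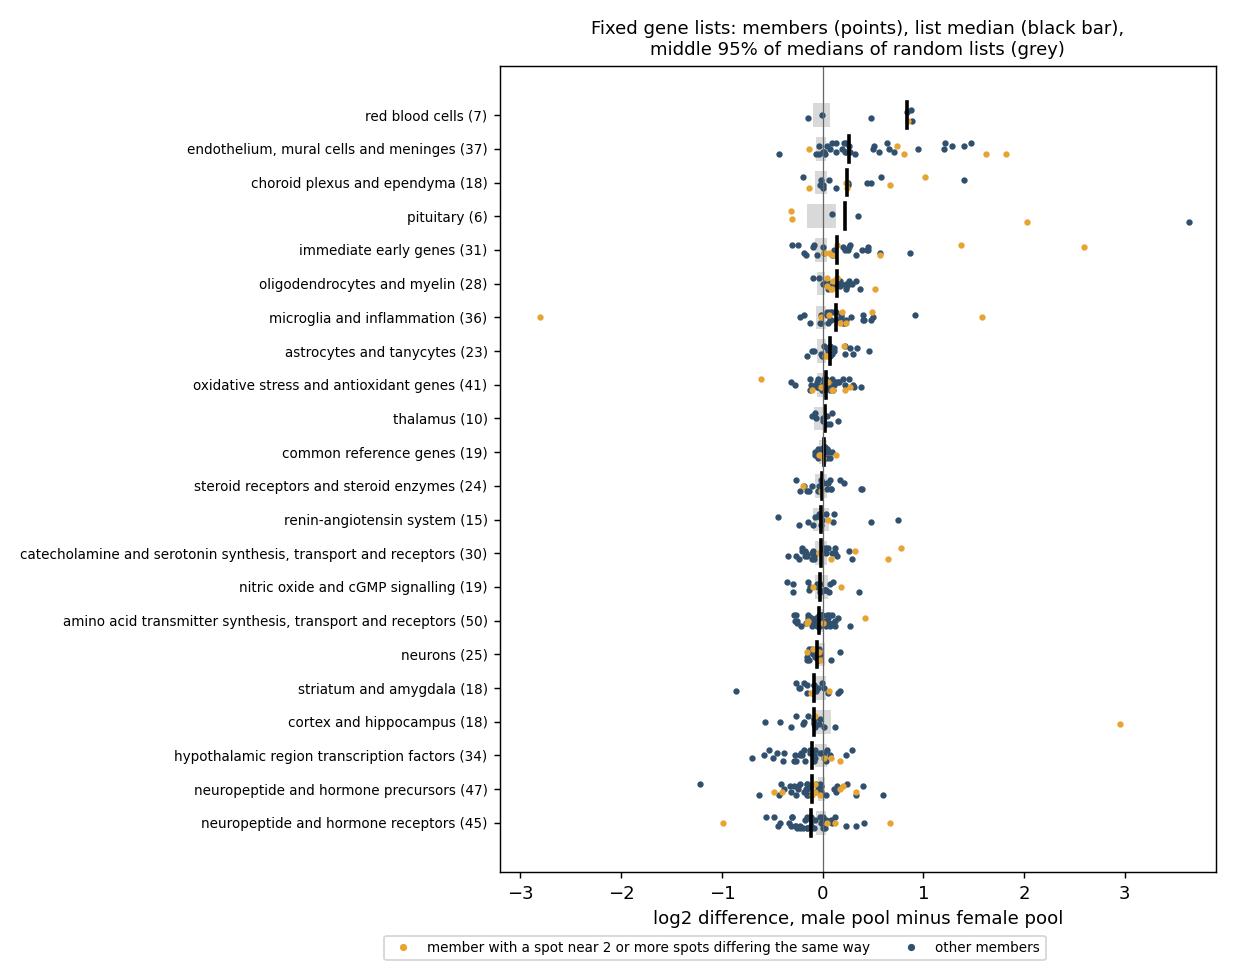
Log2 differences (x axis, male minus female) of the members of each fixed list well above background on both arrays (points; orange, at least 1 spot in a patch), list medians (black bars) and the middle 95% of 10000 random list medians (grey), with the number of members beside each list. Medians run from -0.11 for neuropeptide receptors to 0.84 for red blood cells.

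The named genes with the largest differences on both arrays lay almost all in patches. In the male direction they were Wnt10b (4.56), Txnrd3, Tshb, Or6x1, Zfp831, Vdr (3.54), Slc47a2, Il36a, Ikzf2, Dus4l, Cux2 and Ireb2 (2.90). In the female direction they were Rpl39l5 (-4.54), Veph1, Or9e1, Rpl39l1, Efna4, Or13a27e, Lingo3, Tnf, Car6, Ankrd34c, Fer and Tmem86b (-2.47). All 24 were single-spot probes, and 23 of them, all except Tshb, were in patches. Among genes well above background in 1 pool only, the largest bounds were those of Eif2s3y, H2ac1, Gabrr3 and Or2a7 in the male pool and Tex13c, Clca1, Six6 and Krt76 in the female pool, all in patches except Eif2s3y.

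Outside patches, the rule named other genes, and several had repeat spots or a second probe. Nupr1, a stress-induced regulator of transcription, was 4.56-fold higher in the male pool over 8 spots. This is a log2 difference of 2.19, and its second probe was at 2.21. Hspa1a, the inducible heat shock protein 70 gene, was 3.96-fold higher, and 4.93-fold higher on its second probe. Ptgds, the prostaglandin D synthase of meninges and choroid plexus, was 2.86-fold higher over 9 spots, and Sfrp1, a secreted Wnt inhibitor gene, was at 1.49 with its second probe at 1.16. The remaining male-direction genes were Tshb, Ogn, Cd74 and Ddx3y, and on single spots Plac9 (1.79), the carboxypeptidase-like gene Cpxm2 (1.67), the chemokine gene Ccl19 (1.58) and the mesenchymal transcription factor gene Foxc2 (1.49). Lower in the male pool, all on single spots, were Snai3 (-1.98), the glycogen phosphorylase kinase gene Phka1 (-1.50), Dio3, which encodes the enzyme that inactivates thyroid hormone (-1.40), the keratin gene Krt42 (-1.37), Kiss1 (-1.22), Plscr1 (-1.18) and Slc17a4 (-1.15). Tdrd5, Msl3, Prss41, Hsd17b13 and S100g followed, between -0.92 and -0.74, with Msl3 at -0.05 when all spots were used. With normexp, whose offset shrinks the differences of dim genes by construction, 24 of 74 named genes at least 2-fold apart fell under 2-fold. In the female direction these were Snai3, Phka1, Dio3, Krt42, Kiss1, Plscr1, Slc17a4, Fcgbp, Fer, Hsd3b1, Oasl and Or2ah1, and in the male direction Cd74, Col3a1, Cpxm2, Fosl1, Foxc2, Gabre, Gclm, Gucy2c, Kcnj13, Plac9, RT1-Da and Sfrp1. The largest bounds outside patches were Eif2s3y, Gja3, Apob and Or1j13c in the male pool and 1700012B07Rkl, Or2ah1, Oasl and Fcgbp in the female pool. All but Or1j13c and Fcgbp had a single 2-fold neighbour of their direction, under the minimum of 2 for a patch. Gja3 and Apob were each that neighbour of the other. Apob, 1700012B07Rkl, Or2ah1 and Oasl differed by fewer signal units than the neighbour, and Eif2s3y and Gja3 by more. The second Gja3 probe was at a bound of -0.30 in the other direction, and the second Apob probe was not well above background on either array.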

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

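Normexp correction on the spot medians and both patch settings were chosen after seeing the data; the planned normexp run on spot means could not be made because the files hold no such column, and slide and scan could not be a block because both arrays shared them. No paired analysis was possible because each sex had 1 pool. No called result reversed; the medians of steroid, thalamus and reference genes, near 0, changed sign. Of 28 values for counts 15 stayed within 1.5 times the main count, of 239 list medians 194 moved by less than 1 SD of random lists, and of 1477 single-gene values 1347 moved by less than 1 technical SD. With normexp, however, 98 of 174 genes moved by more: Kiss1 was at -0.40, Dio3 at -0.46 and Tshb at 1.80. Loess centring and kept outlier spots left every count and every fixed list's median within those limits. The matrix values did so too, but they repeat the main scaling. Their agreement was fixed in advance and adds to the totals above without testing them. The X-linked median ran from -0.070 with median centring to -0.016 with normexp. Signal over background limits the dim genes, and 26109 of 39500 genes were measured. Of the 1090 genes at least 2-fold apart, 972 had a mean log2 signal of -4 or lower, to which a low signal on 1 array contributes.

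Counts in the male and female pools were 1074 and 711 at 1.5-fold, 278 and 148 with both arrays above background, 1481 and 1172 with no filter, and 305 and 186 with normexp. They were 108 and 31 outside patches, and 152 and 51 with a minimum of 3 neighbours, and 433 and 298 at 3-fold. The thresholds and filters act by their construction. So does the offset of 50 units in normexp, which shrinks the log differences of dim genes. Normexp changed the signal column, the background correction and the offset together, and their shares were not tested.

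With normexp, medians were -0.067 for precursors, -0.065 for receptors, 0.038 for steroid genes (from -0.010), -0.020 for amino acid transmitters, 0.057 for oxidative stress, -0.058 for transcription factors, -0.038 for cortex, -0.058 for striatum, 0.13 for choroid plexus, 0.22 for endothelium and meninges, and 0.45 for red blood cells. Percentiles were 1.68 for cortex and 2.71 for striatum. With median centring, medians were -0.14 for precursors, -0.15 for receptors, -0.050 for catecholamine genes, -0.071 for amino acid transmitters, 0.0016 for oxidative stress, 0.10 for microglia, 0.11 for immediate early genes, -0.12 for striatum, 0.11 for oligodendrocytes, 0.039 for astrocytes, -0.091 for neurons, 0.23 for endothelium and meninges, and -0.012 for reference genes. With quantile normalization receptors were at -0.16 and the cortex percentile was 2.47. With the mean over probes, medians were -0.060 for catecholamine genes, 0.21 for immediate early genes, 0.95 for pituitary, -0.016 for thalamus, 0.18 for choroid plexus and 0.23 for endothelium and meninges. With dim members at their bound, medians were 0.18 for microglia, 0.095 for pituitary (percentile 92.8) and 0.76 for red blood cells. Without signal matching the percentile was 2.25 for cortex and 6.75 for neurons. Outside patches, catecholamine genes were at -0.089 (percentile 0.89) and transcription factors at -0.15. With a minimum of 3 neighbours, precursors were at -0.075, catecholamine genes at -0.085 (percentile 0.90) and pituitary at 0.095 (percentile 90.5). Median centring moved the difference of every gene by the same constant, with the median over all genes at -0.047 against -0.016 in the main scaling. It therefore did not move a list relative to other genes, and no list percentile changed its label. The causes of the other shifts were not tested.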

Other observations

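The genes and values in this part were picked after the results were seen, and so were its tests, except those of the second list of meningeal genes and of repeat spots in patches, which were written before their values were seen. Outside the fixed lists, Hspb1, which encodes a small heat shock protein, was 1.85-fold higher in the male pool over 10 spots. Hsp90aa1, which encodes the inducible form of heat shock protein 90, was at 0.04 and -0.04 on its 2 probes. Of the immediate early genes, the phosphatase gene Dusp1 was at 0.27 and the transcription factor genes Klf4 and Egr1 at 0.26 and 0.44.

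Further genes of the neuropeptide lists went both ways. Among receptor genes, Kiss1r for kisspeptin was at -0.28, Tacr3 for neurokinin B at -0.32, Trhr for thyrotropin-releasing hormone at -0.42, and Hcrtr1 and Hcrtr2 for orexins at -0.10 and -0.48. The vasopressin receptor gene Avpr2 was at 0.41 and the endothelin receptor gene Ednra at 0.33, the first within its technical SD of 0.46. With normexp Kiss1r, Tacr3, Trhr, Hcrtr2, Avpr2 and Ednra were at -0.16, -0.17, -0.22, -0.18, 0.23 and 0.14. Among precursors, Nts, the neurotensin gene, was at -0.39 and the growth factor gene Bdnf at -0.41 (-0.21 with normexp), while the neuromedin gene Nmb was at 0.33 and the endothelin gene Edn3 at 0.40.

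Spots at least 2-fold apart lay in patches on the slide. Of 1644 such spots, outlier spots included, 1219 had at least 2 similar neighbours, against 113 to 181 in 100 shuffles of position. Signal added locally on 1 array is a candidate explanation: of 318 repeat spots in patches, 21.4% were at least 50 units above the same probe's median outside patches on the patch's array, against 8.81% on the other array and 8.23% outside patches. A sex difference of the genes printed there is argued against by their second probes, printed elsewhere: 9 of 60 (15%) differed at least 2-fold the same way, against 15 of 23 (65.2%) outside patches. What caused the patches, and whether single genes in them also differ between the sexes, stays open.

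Genes of the meninges were higher in the male pool. The median of the vessel and meninges list without spots in patches was 0.26, above the range of random lists (-0.070 to 0.027). A median moves little when few genes are dropped, so it tests local signal weakly. The 11 fibroblast genes measured outside patches were also all higher, from 0.50 to 1.60, which argues against signal in the patches as their source. Local signal outside patches is not excluded, since in the simulation 263 of 317 affected spots were found in patches. A lower share of neurons alone is argued against because the highest median of the oligodendrocyte, astrocyte and microglia lists, 0.14, was below the lowest of the 13 fibroblast genes, 0.50. More meningeal tissue in the male pool is a candidate explanation: a second list of meningeal genes had a median of 0.457 (22 of 23 higher, random range -0.082 to 0.045), with the transporter gene Slc13a3 at 175% of the 75th percentile in the male pool and 115% in the female pool; none of its genes was in a fixed list. A difference between the sexes in these cells stays open and untested, and with pooled RNA 1 of the 5 rats might account for it.

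Tshb and Cga were higher in the male pool. Cga differed by 1412 units, against at most 158 units for a 2-fold spot near it, and no 2-fold spot lay near Tshb. This cannot exclude an artefact on the single spot of each gene, so local signal stays open. Some genes in patches, such as Wnt10b (346 against 250 units), also exceeded the 2-fold spots near them. Anterior pituitary tissue is argued against because 0 of Gh1 and Prl, the abundant hormone transcripts of that lobe, were well above background in the male pool, if their single probes can detect them. Thyrotropin acting on tanycytes, which raises Dio2 and lowers Dio3, stays open: Dio2 was at 0.30 and Dio3 at -1.40, both beyond their technical SD of 0.20, which leaves out the spread between animals and arrays, but at 0.17 and -0.46 with normexp. Another source, such as the pars tuberalis, where the melatonin receptor gene Mtnr1a at 0.12 was within its technical SD of 0.46, and a sex difference both stay open.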
